A study of Mus musculus musculus x M. m. domesticus and Mus musculus musculus x Mus musculus castaneus and Mus musculus domesticus with 42 samples.

How the data were processed

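The samples were brain, liver and testis of 14 males, 2 from each of 7 genotypes, with 1 array per tissue and male and 42 arrays in all. Genotype, tissue, replicate number and age were taken from the labels, which describe the replicates as separate males. Each genotype was sampled at a single age. Musculus and castaneus shared theirs, as did the musculus x domesticus and musculus x castaneus F1. The difference of domesticus from musculus, the reciprocal differences and those of the F1 from their parents are between different ages and also contain any effect of age.

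The deposited values are intensity on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version, the scanner settings and the detection calls are not given in the sources used here. The mean of each array after trimming 2% at each end lay between 497.75 and 503.63, so the arrays had been scaled to a shared target near 500 before deposit. Median signals ranged from 95 to 183 across arrays. Such scaling leaves differences in the shape of the distribution, which quantile normalization of the 14 arrays of a tissue, an alternative, removes. In all, 1063 values were listed as 0. MAS5 subtracts the signal of mismatch probes and reads each probe set as 1 value, so a sequence difference between a subspecies and the probes can lower a signal with no change in transcript level. The number of arrays limits the precision of every value.

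Of 45037 probe sets, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 had none. The symbols covered 18193 distinct names, and no gene was named from a probe set with several. No genome or chromosome annotation was used, so no positions are given. The planned split of reciprocal differences by chromosome used a list of X-linked genes written by hand after the files were opened but before any contrast was computed, and a fit without sex-linked and mitochondrial probe sets, which needs positions, was not run.

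Signals were taken as log2(signal + 31), where 31 is the 20th percentile of all values. Log2 differences are on that scale and understate the change of dim transcripts. In each tissue, the 27022 probe sets at or above the 40th percentile of the mean log2 value were tested, which corresponds to mean signals of 100, 82.4 and 84.3 in brain, liver and testis and to 13110, 13421 and 14059 distinct genes. Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over its 14 arrays, with genotype as the factor and 7 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each contrast and tissue, and a call is an adjusted p under 0.05. All adjusted p-values of single genes come from limma and are two-sided.

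The parental difference is domesticus or castaneus minus musculus. Nonadditive expression was tested among probe sets with a parental call, as the mean of both reciprocal F1 minus the mean of both parents. Transgressive expression was tested among the remaining probe sets, where the mean of both F1 had to lie above both parents or below both, with the larger of the 2 p-values kept. The reciprocal difference is the F1 with a musculus mother minus the F1 with a musculus father. Dependence on tissue was tested over the 20178 probe sets tested in every tissue, with an F test of the interaction contrasts on all 42 arrays and the animal as a block (estimated correlation 0.293). Arrays of 1 animal deviated together across tissues: 21 of 21 correlations of deviations from the group means lay above 0.1, from 0.159 to 0.476. The pairing of tissues comes from the genotype and replicate number in the labels.

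The 36 gene lists were fixed before the data were examined. A gene was represented by its probe set with the highest mean in the tissue, and a list needed 5 tested genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma. List p-values were adjusted over the lists of a contrast and tissue. The lists of mitochondrially encoded transcripts (0 genes with a probe set), major urinary proteins (3) and pituitary genes had too few tested genes, as did Y-linked genes in brain and liver, and were not tested there.

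Named genes followed a rule set before the data were examined: exactly 1 symbol, no probe set with the suffix _x_at, an adjusted p under 0.05, no overlap between the arrays of the groups compared, and the probe set with the smallest p for each gene. From these came the 6 largest parental differences in each direction per tissue and cross, the 6 largest absolute nonadditive, transgressive and reciprocal differences, and the 6 genes per cross with the largest smallest difference across the 3 tissues. The text prints part of them. Members of the lists were named as examples, and the Y-linked genes as a check of the labels. Where the median of the other tested probe sets of a gene named by size lay at under 25% of its difference, or across 0 from it, a limit chosen after the data were seen, that median is given. Other probe sets were not compared for list members or for genes with opposite signs in different tissues.

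Each step was tested on simulated data built from the real arrays with known changes. Parental changes of log2 0.5, 1 and 2 were recovered at 2.99%, 31.3% and 87.9% in brain, 1.49%, 13.4% and 69.7% in liver, and 0%, 50.7% and 84.8% in testis. Reciprocal changes of log2 0.5, 1 and 2 were recovered at 2.99%, 32.8% and 90.9% in brain, 0%, 10.4% and 84.8% in liver, and 0%, 50.7% and 89.4% in testis. Each of these simulations changed only 67, 67 and 66 of 27022 probe sets at the 3 sizes. Every parental contrast of the data called far more. The adjustment is then less strict, so recovery there can be higher. Nonadditive changes of log2 1, between parents set log2 2 apart, were recovered at 88.5%, 81% and 86%. In the data the median parental difference among calls was smaller, from 0.986 to 1.36, so nonadditive recovery there can be lower. Transgressive changes of log2 1 were recovered at 47%, 20% and 40%. Tissue dependence of log2 1 and 2 was recovered at 41% and 89%. In simulated testis F1 placed at the linear midparent of parents that differed by log2 3, 92.3% were called against the log2 midparent and 0% against the linear one.

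Alternatives set before the data were examined were an offset of 1, quantile normalization, no filter, no intensity trend, the 8 arrays of the cross alone, the replicate number as a block, no animal block, each F1 alone, adjustment over all tested probe sets, and each array left out in turn. Chosen after the data were seen were the midparent on the linear scale, the gene lists for each F1 alone, and the tissue dependence of reciprocal differences with its alternatives. The share of spermatids in testis was tested in 2 versions, with and without the pachytene spermatocyte list, both chosen after the data were seen. The limit for excluding the effect of the maternal X chromosome was written beforehand as a slope under 0.25, and the demand that its whole interval lie under 0.25 was added after the slopes were seen.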

Results

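Transcript levels were measured in brain, liver and testis of 14 male mice on 42 1-colour Affymetrix arrays. The males came from 7 genotypes with 2 males each: the house mouse subspecies Mus musculus domesticus, M. m. musculus and M. m. castaneus, and the 4 reciprocal F1 hybrids of musculus with domesticus or castaneus. Each F1 is written with the mother first. Each genotype was sampled at a single age: 45 days in domesticus, 47 in musculus and castaneus, 53 in the musculus x domesticus and musculus x castaneus F1, 50 in the domesticus x musculus F1 and 54 in the castaneus x musculus F1, so age and genotype are confounded in the parental comparison of domesticus with musculus, in both reciprocal comparisons and in those of the F1 with their parents. The series asks which transcripts differ between the parents of each cross, how the F1 express those transcripts, and which transcripts leave the range of both parents only in the F1. The number of arrays limits the precision of every value below. Replicates correlated across probe sets with Pearson's r of 0.951 to 0.979, and the SD of their log2 difference was 0.32 to 0.575. Y-linked genes served as a check of sex. Eif2s3y, Uty and Uba1y lay above the offset of 31 signal units on 14 of 14 arrays of brain and testis, and 1 Uba1y probe set did so on 13 of 14 liver arrays. That alone says little, since at least 73.2% of all probe sets did so on each array and dim ones had been filtered out. The brightest Eif2s3y probe set had at least 934, 1569 and 907 on every array of brain, liver and testis. No females were sampled for comparison.

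In brain, Snhg14, the host transcript of an imprinted small nucleolar RNA cluster, had a signal of 2978 ± 480 in domesticus and 65.5 ± 16.3 in musculus (SD, n = 2), a log2 difference of 4.96 ± 0.675 (SE, adjusted p = 0.00096). Ncam1, a neural adhesion molecule, and Zyg11b were higher in domesticus by 4.21 and 3.88. Trappc2, an X-linked vesicle trafficking gene, had 2926 ± 227 in musculus and 58.5 ± 9.19 in domesticus, a difference of -5.05 ± 0.151 (adjusted p = 9.5e-09). Lsm14a, an RNA-binding protein of processing bodies, and the neurotrophin receptor Ntrk3 were lower in domesticus by log2 differences of -4.42 and -3.92. Other probe sets of several of these genes lay near 0: 4 other Ncam1 probe sets had a median difference of 0.08, 2 of Zyg11b one of 0.11, 2 of Lsm14a one of -0.07 and 5 of Ntrk3 one of 0.27, and the other Snhg14 probe set was at -0.83. Castaneus brain exceeded musculus brain most in Mid1, a ubiquitin ligase gene at the X pseudoautosomal boundary (2257 ± 478 against 28.5 ± 10.6, log2 difference 5.26 ± 0.278, adjusted p = 2.08e-06), and in Dck, deoxycytidine kinase (4.02, with a median of 0.89 over 2 other probe sets). Xbp1, a transcription factor of the unfolded protein response, was lower in castaneus (-3.43 ± 0.168, with a median of -0.23 over 3 other probe sets), as was Fxyd2, a sodium pump regulator (-2.93).

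Across the brain, 1553 of 27022 probe sets (5.75%) differed between domesticus and musculus, 882 of them higher in domesticus and 671 higher in musculus. Between castaneus and musculus, 1640 (6.07%) differed, 842 higher in castaneus and 798 higher in musculus. Of 14 choroid plexus genes, 3 rose in domesticus over all genes tested and 5 when adjusted over the list alone, none falling in either. Kl, an anti-ageing membrane protein, rose by 1.34, Steap1 by 1.21 and Sostdc1 by 0.87, with a list adjusted p of 4.44e-05 and an adjusted p = 0.0733 with an estimated correlation. Of 25 interferon response genes, 6 rose and 1 fell in castaneus (9 and 1 adjusted over the list alone). Ifi27 rose by 3.60, Rtp4 by 2.34 and Ifit3 by 1.35, and Ifit2 fell by 1.07. That list had an adjusted p of 1.15e-05 and an adjusted p = 0.754 with an estimated correlation. Leaving out any single parental array left 700 to 853 domesticus calls (700 without musculus replicate 1, 708 without musculus replicate 2, 832 without domesticus replicate 2, 853 without domesticus replicate 1) and 724 to 1084 castaneus calls (724 and 730 without musculus replicates 1 and 2, 1084 and 793 without castaneus replicates 1 and 2). Both crosses share the musculus arrays, so a gene named in both is not independent evidence.

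In liver, Enho, which encodes the peptide adropin, had a signal of 2448 ± 712 in domesticus and 11.5 ± 0.707 in musculus (SD, n = 2), a log2 difference of 5.84 ± 0.308 (SE, adjusted p = 1.77e-07). Ifi27, an interferon-induced gene, rose by 4.99 and Glyctk, glycerate kinase, by 4.73, while the other Glyctk probe set was at 0.12. Tff3, a secreted trefoil peptide, Akr1c18, a steroid-metabolising reductase, and Dntt, a DNA polymerase of lymphoid cells, were lower in domesticus, by -5.19 ± 0.448, -5.14 ± 0.216 and -4.92 ± 0.362. Sult2a2, a hydroxysteroid sulfotransferase, had the largest fall (-6.79) with a wide error (SE 1.8, adjusted p = 0.0427). In castaneus, Moxd1, a monooxygenase, reached 22380 ± 281 against 9.5 ± 0.707 in musculus, a difference of 9.11 ± 0.939 (adjusted p = 7.66e-05). The sulfotransferase Sult3a1 rose by 7.91 ± 0.418, the carboxylesterase Ces2b by 5.23 and carbonic anhydrase Car2 by 5.21. Mrap, a melanocortin receptor accessory protein, was lower by -5.95 ± 0.219, Ces2e by -5.32 and the bile acid transporter Slc10a2 by -4.65.

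Interferon response genes rose as a group in castaneus liver. Of 34, 22 rose and none fell in castaneus (28 and 1 adjusted over the list alone), with a median log2 difference of 1.34. Oas1a rose by 3.14, Ifit1 by 2.93, Mx1 by 2.52 and Igtp by 2.29. The list adjusted p was 1.45e-23, with an adjusted p = 0.0452 with an estimated correlation, and 3 of the 76 list calls held with one. Of 12 genes of antigen presentation, 5 rose in castaneus (7 up and 1 down adjusted over the list alone), among them H2-D1 (3.17) and the immunoproteasome genes Psmb9 (2.44) and Psmb8 (1.98), with an adjusted p = 0.336 with an estimated correlation. Of 20 cholesterol synthesis and uptake genes, 9 rose in castaneus (12 adjusted over the list alone), including Hsd17b7 (1.65), Cyp51 (1.59), Dhcr7 (1.30) and Sqle (1.28), also with an adjusted p = 0.336 with an estimated correlation. Cytochrome P450 genes went both ways: of 43, 6 rose and 3 fell in domesticus (8 and 3 adjusted over the list alone), with Cyp17a1 at 3.83, Cyp2b9 at 2.88 and Cyp46a1 at -2.50, and an adjusted p = 0.773 with an estimated correlation. In castaneus, 8 of them rose and 6 fell (11 and 7 adjusted over the list alone, adjusted p = 0.813 with an estimated correlation). After quantile normalization the P450 list had an adjusted p of 0.229 in domesticus and 0.327 in castaneus. Of 19 fatty acid synthesis genes, 3 fell and none rose in domesticus (7 adjusted over the list alone), with Pnpla3 at -2.83, Me1 at -1.16 and Acsl5 at -0.76, and an adjusted p = 0.773 with an estimated correlation.

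The liver total was 1668 probe sets (6.17%) in domesticus against musculus, 854 higher and 814 lower in domesticus, and 1771 (6.55%) in castaneus against musculus, 849 higher and 922 lower in castaneus. Without musculus replicate 1 the counts were 769 and 745. Without musculus replicate 2 the domesticus count was 1085, and without castaneus replicates 1 and 2 the castaneus count was 1097 and 1162.

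In testis, 1700029F12Rik had a signal of 5908 ± 977 in domesticus and 28.5 ± 3.54 in musculus (SD, n = 2), a log2 difference of 6.63 ± 0.186 (SE, adjusted p = 1.28e-10), and it also rose in castaneus (5.92). Lpcat2b, a lysophospholipid acyltransferase, rose by 6.41 ± 0.263 in domesticus and also in castaneus (63.8-fold, adjusted p = 1.4e-08), and Ttc30a2, a ciliary transport protein, by 5.99 in domesticus. The complement component C8b (-5.05), Stac (-4.98) and the carboxypeptidase Cpn1 (-4.90 ± 0.185) were lower in domesticus. Castaneus testis was higher in the carboxylesterase Ces1c (1446 ± 146 against 5 ± 1.41, log2 difference 5.36 ± 0.231), in Steap1 (4.51) and in Fabp4, a fatty acid binding protein of adipocytes (4.38). H2-Bl, of MHC class I (-4.69), and the surface protein Cd24a (-4.50) were lower there.

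Leydig cell genes differed in both crosses. Of 16, 6 rose and 1 fell in domesticus (7 and 1 adjusted over the list alone), including the angiotensin precursor Agt (adjusted p = 6.58e-06), Klk1b24 (2.68) and Cyp17a1 (1.35), and Hsd3b1 fell by 1.03. The list adjusted p was 0.0348, with an adjusted p = 0.941 with an estimated correlation. In castaneus 5 rose and none fell (6 adjusted over the list alone), with Klk1b24 at 4.31, Ptgds at 1.70 and Cyp17a1 at 1.49, an adjusted p of 0.0094 and an adjusted p = 0.524 with an estimated correlation. The testis had 3460 calls (12.8%) in domesticus against musculus, 1877 higher and 1583 lower in domesticus, and 3642 (13.5%) in castaneus against musculus, 2022 higher and 1620 lower in castaneus. Leaving out domesticus replicate 1 or 2 or musculus replicate 1 or 2 gave 2166, 2039, 2212 and 2265 domesticus calls. Leaving out musculus replicate 1 or 2 or castaneus replicate 1 or 2 gave 2310, 2356, 2291 and 2130 castaneus calls.

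**Figure D1:**
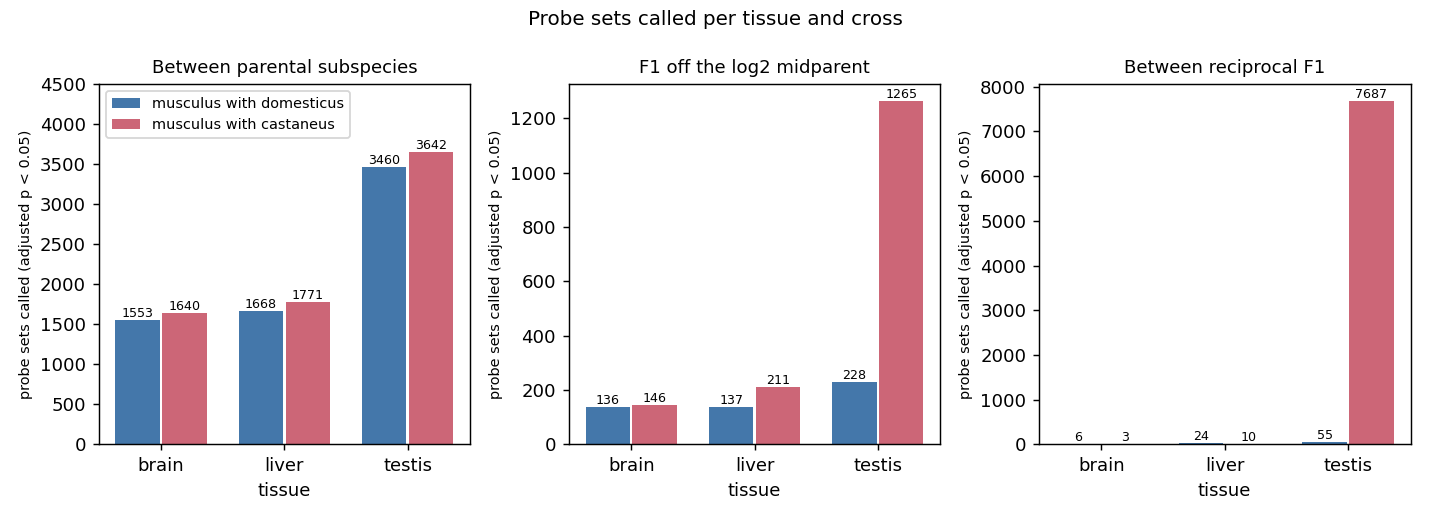
Number of probe sets called by limma (vertical axes, starting at 0) in brain, liver and testis, with 1 bar per cross, between the parents (left panel), for F1 off the log2 midparent (middle) and between reciprocal F1 (right). Parental calls range from 1553 to 3642, and the reciprocal F1 of the castaneus cross reach 7687 in testis against 3 in brain and 10 in liver.

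Parental differences were tested for dependence on tissue over the 20178 probe sets tested in all 3 tissues. Mid1 was higher in castaneus than in musculus by 5.26 in brain, 4.81 in liver and 3.99 in testis, and Dck by 4.02, 2.70 and 2.93. Ythdc1, a reader of methylated RNA, was higher in domesticus by 3.18, 2.82 and 3.10 (SE 0.243, 0.274 and 0.225), and the chaperonin subunit Cct6a by 2.68, 2.93 and 2.72. Lsm14a was lower in domesticus in all 3 tissues (-4.42, -3.14 and -2.52). These values rest on 1 probe set per gene, and the others differed far less. The other Ythdc1 probe set was at 0.45, 0.19 and 0.22 and that of Cct6a at 0.44, 0.61 and 0.41. The 2 other probe sets of Dck had medians of 0.89, -0.16 and 0.19, those of Lsm14a -0.07, 0.17 and -0.14, and those of Mid1 0.08 in liver. In domesticus, 229 probe sets were called in all 3 tissues with 1 sign, where independent calls would give 6.75 in all 3 tissues, and in castaneus 242, where they would give 7.77. The 3 tissues came from the same males, so their calls are not independent and these reference counts are too low.

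**Figure D2:**
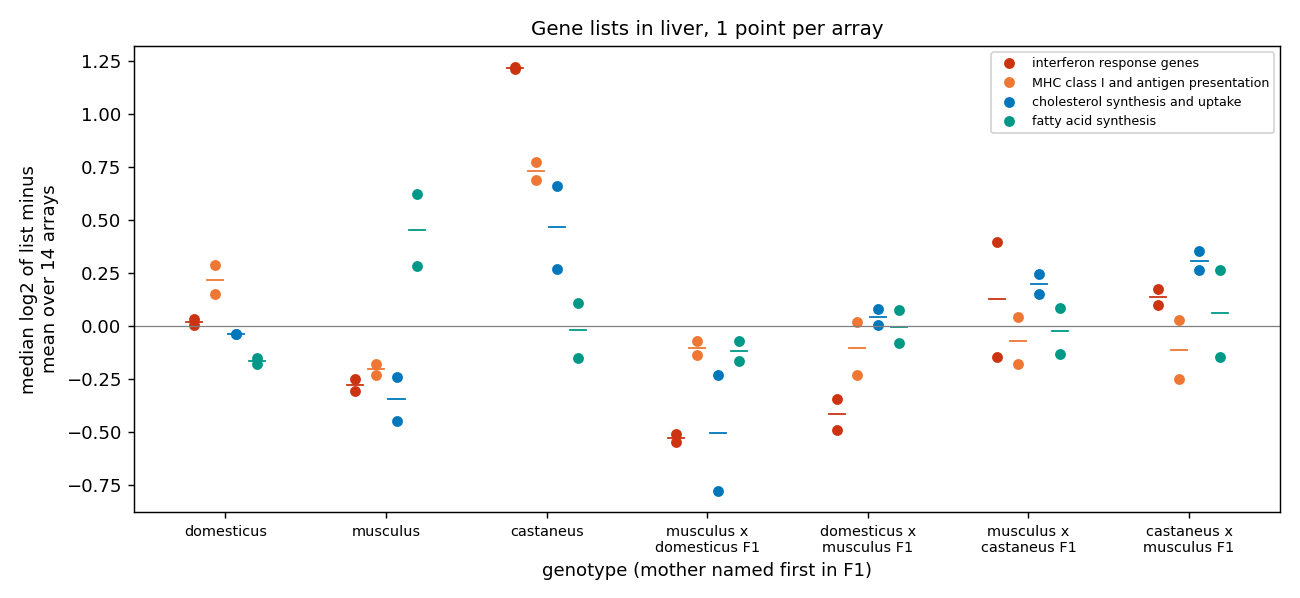
Liver gene lists by genotype (horizontal axis): each point is 1 array's median over the list's genes of log2 signal minus that gene's mean over the 14 liver arrays (vertical axis), short lines are the mean of the 2 arrays, and colours are the interferon, antigen presentation, cholesterol and fatty acid synthesis lists. The interferon list is at 1.21 and 1.22 in castaneus, 0.03 and 0.00373 in domesticus and -0.31 and -0.25 in musculus.

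Nonadditive expression compares the mean of both reciprocal F1 with the mean of the parents on the log2 scale, among transcripts that differ between those parents. In liver, Tff3 of the domesticus cross lay 2.89 ± 0.316 above the midparent (SE, adjusted p = 7.38e-05), with F1 signals of 13170 ± 1655 and 12500 ± 1082 (SD, n = 2) near the musculus 10830 ± 3950 rather than the domesticus 256 ± 24. Enho lay 2.04 and Wdfy1 2.06 above it, with a median of 0.05 over 3 other Wdfy1 probe sets. In the castaneus cross, Moxd1 lay 3.63 ± 0.664 and Sult3a1 3.57 ± 0.296 above the midparent, and the antiviral Oas1a lay below it (-2.25 ± 0.524, adjusted p = 0.0138) with 457 ± 484 and 166 ± 129 in the F1 against 3470 ± 53.7 in castaneus. In brain, Ncam1 (1.43) and Rab10os (1.35) led the domesticus cross, and Pisd-ps3 (1.90) and Dck (1.46) the castaneus cross, in which Dusp19 lay below (-1.27). Other probe sets of Ncam1, Pisd-ps3 and Dck had medians of -0.03, 0.05 and 0.06. In testis, Ttc30a2 (2.82 ± 0.174) and 1700029F12Rik (2.51 ± 0.132) led the domesticus cross, and Lpcat2b (1.82 ± 0.186) and the steroidogenic cholesterol carrier Star (1.42 ± 0.236) were among the leading genes of the castaneus cross. Against a midparent taken on the linear scale, an alternative chosen after the data were seen, 27 of the 36 named nonadditive calls were lost, 2 of them with a change of sign. Lpcat2b turned to -0.20, and Tff3 (1.25), Enho (0.10), Moxd1 (0.07), Sult3a1 (0.61), Ncam1 (0.25), Rab10os (0.49), Pisd-ps3 (1.26), Dck (0.37), Ttc30a2 (0.80) and 1700029F12Rik (0.18) were no longer called. Wdfy1 (0.90), Oas1a (-2.98), Dusp19 (-1.50) and Star (0.96) stayed called.

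In brain, liver and testis, 136, 137 and 228 probe sets were nonadditive in the domesticus cross, of which 133, 122 and 221 lay above the midparent. The castaneus cross gave 146, 211 and 1265, of which 135, 184 and 829 lay above. Against the linear midparent the domesticus counts were 2, 28 and 14 and the castaneus counts 10, 61 and 1126. Of these, 0, 6 and 8 lay above it in the domesticus cross and 1, 16 and 499 in the castaneus cross. Among parental calls that were not nonadditive, the 95% interval of F1 minus midparent lay inside the parental range for 928, 897 and 1827 of the domesticus cross and 858, 908 and 1181 of the castaneus cross. The rest, 489, 634 and 1405 in the domesticus cross and 636, 652 and 1196 in the castaneus cross, were undetermined. In the castaneus cross the 25 interferon response genes of brain had a median of -0.42 from the midparent, with 0 called by limma over all genes and 9 lower adjusted over the list alone (adjusted p of 3.13e-16, adjusted p = 0.074 with an estimated correlation). The 31 acute phase and complement genes of its liver had a median of -0.30, with 3 lower (1 higher and 12 lower adjusted over the list alone, adjusted p = 0.37 with an estimated correlation). The brain count of the domesticus cross was 88 without musculus x domesticus F1 replicate 2 and 86 without domesticus x musculus F1 replicate 1, and its liver count was 264 without musculus replicate 2. The testis count of the castaneus cross was 816 and 723 without musculus replicates 1 and 2, and 693 and 621 without castaneus replicates 1 and 2.

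**Figure D3:**
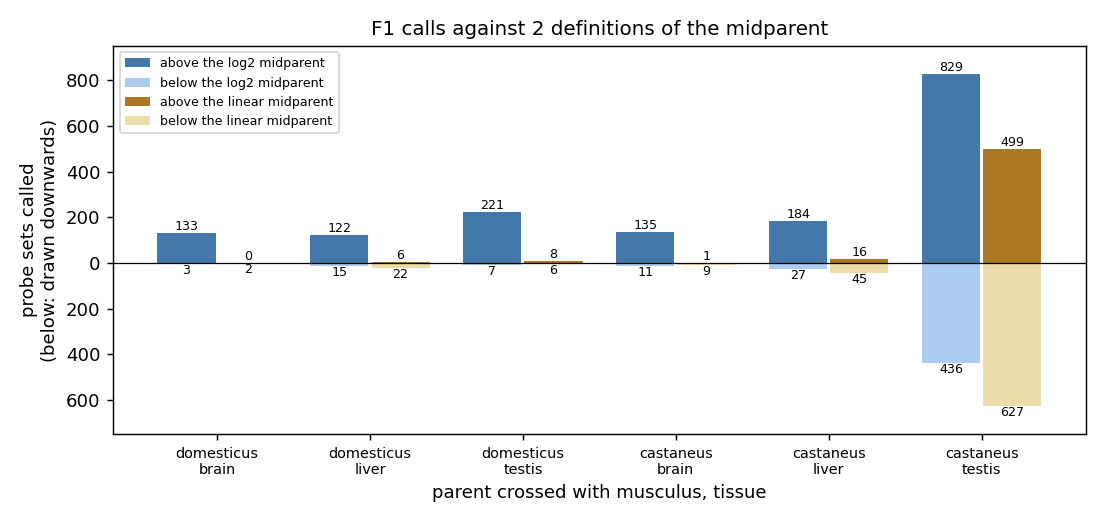
Number of probe sets called off the midparent (vertical axis; calls above are drawn upwards from 0 and calls below downwards) per cross and tissue (horizontal axis), for a midparent on the log2 scale (left bar of each pair) and on the linear scale (right bar). In testis of the castaneus cross 829 lie above and 436 below the log2 midparent, and 499 above and 627 below the linear one.

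Transgressive expression asks for F1 levels outside both parents where the parents do not differ. In testis of the castaneus cross, Neil3, a DNA glycosylase of dividing cells, lay 2.88 above the nearer parent (adjusted p = 5.58e-07), with 898.5 ± 114 and 1248 ± 89.8 in the F1 against 117.5 ± 16.3 in musculus and 114 ± 9.9 in castaneus (SD, n = 2). Homer1, a synaptic scaffold protein, lay below both parents (-1.33, with a median of 0 over 4 other probe sets, where F1 that lie between the parents count as 0). Gsap (-1.30), the Wnt coreceptor Lrp5 (-1.25), Usp50 (-1.17) and Nutm1, a testis nuclear protein (-1.12), also lay below both. Neil3 was called with either F1 alone (2.64 with a musculus mother and 3.11 with a musculus father), and the other 5 genes only with the musculus x castaneus F1 alone. Homer1 had 11.5 ± 7.78 in that F1 and 113 ± 41 in the castaneus x musculus F1, against 162.5 ± 3.54 in musculus, and Usp50 had 845 ± 32.5 and 2360 ± 43.1 against 3231 ± 468. In all, 356 probe sets were called there, 81 above and 275 below both parents. This count rests on the mean of both F1: the musculus x castaneus F1 alone gave 3833, 2117 above and 1716 below, and the castaneus x musculus F1 alone gave 1. Quantile normalization gave 776 and no filter 60. Limma called 0 in brain, liver and testis of the domesticus cross (65, 131 and 71 at an unadjusted p under 0.05) and 0 in brain of the castaneus cross (122 unadjusted), while the liver of that cross had 1 (234 unadjusted), a probe set with no single gene symbol. With only the 8 arrays of the cross, or without an intensity trend, the testis count of 356 was 1. It was also 1 without musculus replicate 1, musculus replicate 2, castaneus replicate 2 or castaneus x musculus F1 replicate 2, and 2 without castaneus replicate 1 or musculus x castaneus F1 replicate 2. The brain count of the castaneus cross was 9 without musculus x castaneus F1 replicate 1, and the liver count was 0 without either musculus replicate or castaneus x musculus F1 replicate 2 and 2 without musculus x castaneus F1 replicate 1 or castaneus x musculus F1 replicate 1.

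Reciprocal F1 differ in which parent was the mother, and all differences are given as F1 with a musculus mother minus F1 with a musculus father. In the domesticus cross, Trappc2 was higher with a musculus mother in brain (2946 ± 17.7 against 110.5 ± 26.2, SD, n = 2, log2 difference 4.41 ± 0.151, adjusted p = 8.96e-08), liver (3.52 ± 0.374) and testis (2.07 ± 0.201). The X-linked nucleotide sugar transporter Slc35a2 (-2.28) and the syntaxin Stx3 (-2.60) were lower in brain, while 5 other Slc35a2 probe sets had a median of -0.02 and 1 of Stx3 had 0.24. In liver, the acute phase protein Orm1 (2.94), the ganglioside synthase St3gal5 (2.26) and the glucocorticoid-induced Fkbp5 (2.21) were higher, and Car5b, a mitochondrial carbonic anhydrase, was lower (-2.31). St3gal5 (4723 ± 284) and Fkbp5 (4306 ± 105) in the musculus x domesticus F1 lay above both parents, and Orm1 did not. The clock gene list was also called in this liver contrast at the preset correlation, and the labels give no hour of collection. In testis, Nmnat3, an enzyme of NAD synthesis, was higher (2.56 ± 0.149) and Zfp185 lower (-2.48 ± 0.317, with -0.24 at its other probe set). Of 19 X-linked germline genes in testis, 2 rose (7 adjusted over the list alone), Ctag2 by 1.19 and Actrt1 by 1.10, with a median of 0.42 (adjusted p = 0.00351 with an estimated correlation). Of 5 Y-linked genes in testis, Zfy2 rose by 1.24 (4 adjusted over the list alone, adjusted p = 0.0289 with an estimated correlation).

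The domesticus cross had 6, 24 and 55 reciprocal calls in brain, liver and testis, of which 4, 13 and 49 were higher with a musculus mother. The brain split turned with no filter (2 higher and 6 lower) and without an intensity trend (2 higher and 3 lower). After quantile normalization the liver calls numbered 36, 14 higher and 22 lower. The brain count was 2 and 3 without musculus x domesticus F1 replicates 1 and 2 and 3 without domesticus x musculus F1 replicate 1. The liver count was 0 and 3 without musculus x domesticus F1 replicates 1 and 2 and 4 and 5 without domesticus x musculus F1 replicates 1 and 2. The testis count was 6 and 18 without musculus x domesticus F1 replicates 1 and 2 and 17 without domesticus x musculus F1 replicate 2.

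In the castaneus cross, reciprocal F1 differed widely in testis. Pmaip1, a proapoptotic BCL2 family member, was higher with a musculus mother (768.5 ± 44.5 against 69 ± 32.5, SD, n = 2, log2 difference 3.04 ± 0.329, adjusted p = 9.12e-05), as were the X-linked copper transporter Atp7a (2.95) and the kallikrein Klk1b24 (2.86), while Rnf24 (-3.02 ± 0.261, with 0.21 at its other probe set) and Lrrc10b (-2.45 ± 0.251) were lower. Round spermatid genes fell as a group: 24 of 26 were lower with a musculus mother (26 adjusted over the list alone), with a median of -0.97 (adjusted p of 3.61e-16, adjusted p = 0.131 with an estimated correlation). Of 33 elongating spermatid genes 20 were lower (23 adjusted over the list alone, median -0.63, adjusted p = 0.322 with an estimated correlation). Of 20 Sertoli cell genes 16 were higher (16 adjusted over the list alone, median 0.70, adjusted p = 0.131 with an estimated correlation), and of 16 Leydig cell genes 9 were higher (12 adjusted over the list alone, median 0.88, adjusted p = 0.306 with an estimated correlation). Of 20 spermatogonial genes 8 were higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p of 0.0438, adjusted p = 0.338 with an estimated correlation, and an adjusted p of 0.0694 after quantile normalization).

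Set against the midparent, a comparison per F1 that was added after the data were seen, the musculus x castaneus F1 lay apart from its parents in the same lists. Of 26 round spermatid genes, 25 were lower than the midparent (26 adjusted over the list alone, quartiles -1.18 and -0.70, adjusted p = 0.159 with an estimated correlation), including Sun5 (-1.53), Izumo1, a sperm protein that binds the egg (-1.43), and Catsper3, a sperm calcium channel (-1.36). Izumo1 had 1388 ± 1.41 with a musculus mother and 3286 ± 609 with a musculus father (SD, n = 2). Of 33 elongating spermatid genes, 26 were lower (29 adjusted over the list alone, median -0.85, adjusted p = 0.272 with an estimated correlation), including Spem1 (-1.45), Tssk6 (-1.30) and Prm3 (-1.20). Sertoli genes were higher in 14 of 20 (15 adjusted over the list alone, median 0.69), among them Cldn11 (1.37), Rhox5 (1.37) and Wt1 (1.05). Leydig genes were higher in 11 of 16 (12 adjusted over the list alone, median 0.92), among them Cyp11a1 (1.42) and Cyp17a1 (1.21). These 2 lists had an adjusted p = 0.159 and an adjusted p = 0.272 with an estimated correlation. Spermatogonial genes were higher in 11 of 20 and lower in 2 (11 and 2 adjusted over the list alone), with Kit at 1.06 and Zbtb16 at -1.42, and an adjusted p = 0.397 with an estimated correlation. Taken alone, the musculus x castaneus F1 had 1911 nonadditive and 3833 transgressive calls in testis, and the castaneus x musculus F1 had 159 and 1. In the castaneus x musculus F1 the medians were -0.01 for round spermatids, -0.20 for elongating spermatids, 0.01 for Sertoli and -0.000956 for Leydig genes.

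**Figure D4:**
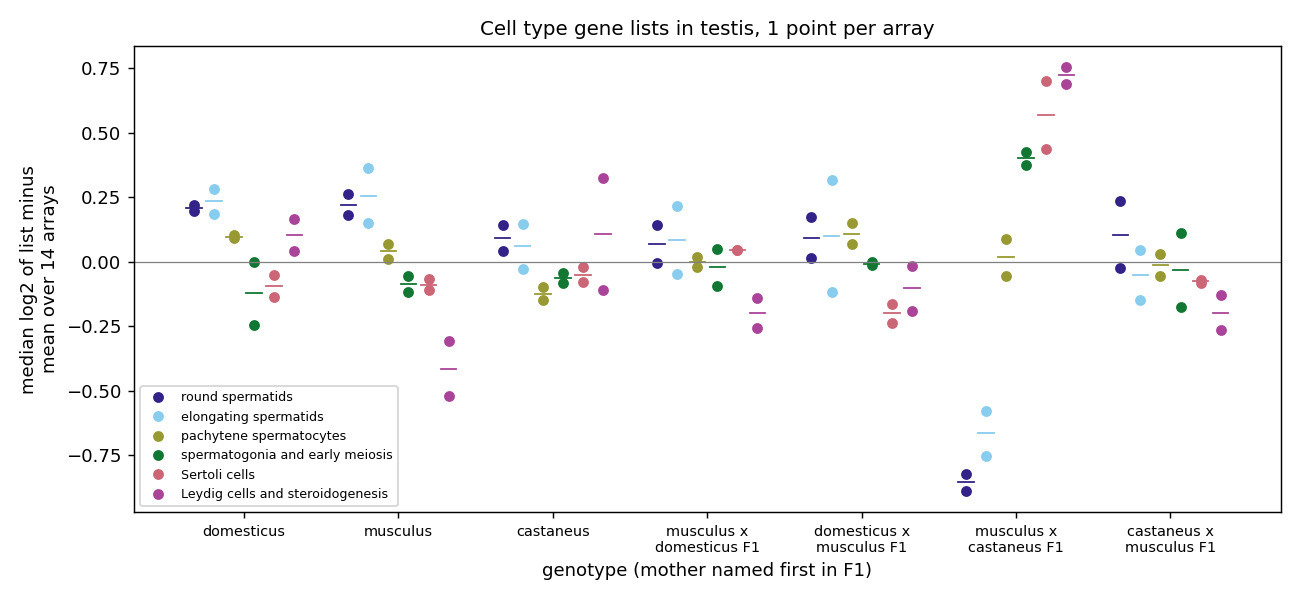
Testis cell type lists by genotype (horizontal axis): each point is 1 array's median over the list's genes of log2 signal minus that gene's mean over the 14 testis arrays (vertical axis), short lines are the mean of the 2 arrays, and colours are the 6 lists. In the musculus x castaneus F1, round spermatid genes are at -0.82 and -0.89 and Sertoli genes at 0.44 and 0.70, and in the castaneus x musculus F1 they are at 0.23 and -0.02 and at -0.08 and -0.07.

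Counts of the castaneus cross were 3, 10 and 7687 in brain, liver and testis, with 3, 7 and 4836 higher with a musculus mother. In testis the reciprocal calls were 28.4% of the probe sets tested, 1951 of them at least 2-fold. After quantile normalization of the testis arrays 6119 were called, 2740 higher and 3379 lower, and the median reciprocal difference over all probe sets tested moved from 0.24 to 0.03, while the 4 spermatid, Sertoli and Leydig lists kept their directions (medians -0.85, -0.50, 0.70 and 0.96). In liver the calls were 11 after quantile normalization, 6 higher and 5 lower. In brain, Mid1 was higher with a musculus mother (2.37 ± 0.278, adjusted p = 0.0234), the other calls there being 1 probe set with no symbol and 1 with several. In liver the X-linked genes Serpina7, a thyroxine carrier (3.52 ± 0.507), Araf, a kinase (2.60, with a median of -0.17 over 4 other probe sets) and Ftsj1, an RNA methyltransferase (1.34, with -0.13 at its other probe set), and the acute phase Saa1 (2.16) were higher with a musculus mother. Exocrine pancreas genes were also higher there (median 2.81 over 12, 0 called by limma over all genes and 10 adjusted over the list alone, adjusted p = 0.687 with an estimated correlation), with Zg16 at 14760 and Prss2 at 7508 on the array of replicate 2 of the musculus x castaneus F1. The testis count was 3664 without musculus x castaneus F1 replicate 2 and 3447 without castaneus x musculus F1 replicate 1, the brain count 52 without musculus x castaneus F1 replicate 1 and 0 without any other array, and the liver count 28 and 1 without musculus x castaneus F1 replicates 1 and 2 and 4 and 0 without castaneus x musculus F1 replicates 1 and 2.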

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

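Chosen only after the results they concern were seen were the tissue test of reciprocal differences, the tests of other probe sets, both tests of the share of spermatids, the regression on both subspecies, the tests of exchanged labels, of array brightness and of age, and the linear midparent; the bounds for direction and for a mislabelled sample were written before their values were computed.

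Many parental differences depended on the tissue. Enho differed in opposite directions: domesticus was higher than musculus in liver (5.84 ± 0.308, SE) and lower in testis (-1.86 ± 0.262), with an interaction adjusted p of 1.63e-15. H2-Bl of MHC class I was higher in domesticus liver (2.26) and lower in domesticus testis (-4.08), and the carbonic anhydrase Car3 was lower in domesticus brain (-1.84) and higher in its testis (1.59). Hebp2, a heme-binding protein, was higher in castaneus liver (2.89) and lower in castaneus testis (-2.66). In all, 63 probe sets in the domesticus cross and 64 in the castaneus cross had calls of opposite sign in different tissues. Such a choice all but implies an interaction, so the interaction p-values of these genes are no further evidence. Over all 20178 probe sets the interaction was called for 2493 and 2784, and for 1304 and 1356 without the animal block. With no filter, over 45037 probe sets, it was called for 3874 and 3930. Without musculus replicates 1 and 2 the domesticus count was 1389 and 1578, and without domesticus replicates 1 and 2 it was 1656 and 1635. The castaneus count was 1416 and 1719 without musculus replicates 1 and 2, and 1545 and 1774 without castaneus replicates 1 and 2.

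Reciprocal differences depended on the tissue for 393 probe sets of the domesticus cross and 3623 of the castaneus cross. Without the animal block the counts were 95 and 1541, and after quantile normalization the castaneus count was 2314. The domesticus count was 85 without musculus x domesticus F1 replicate 1, and 120 and 84 without domesticus x musculus F1 replicates 1 and 2. The castaneus count was 2224 and 1079 without musculus x castaneus F1 replicates 1 and 2, and 830 without castaneus x musculus F1 replicate 1.

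The testis of the musculus x castaneus F1 had lower spermatid and higher Sertoli, Leydig and spermatogonial transcripts than the midparent. These lists were called at a preset correlation, and none was with an estimated one (adjusted p from 0.159 to 0.397). Of 20 spermatogonial genes, 11 were higher and 2 lower. A lower share of spermatids would raise the genes of all other testis cells. The median over all genes was 0.0882. List medians were 0.472 (spermatogonial), 0.687 (Sertoli), 0.92 (Leydig), 0.381 (peritubular and macrophage) and 0.0421 (pachytene spermatocytes). The 5 lists differed from each other (permutation p = 1e-05, the smallest that 100000 permutations can give). So did the 4 lists without pachytene spermatocytes (permutation p = 0.00691), all of which rose, with genes as units although they are not independent. The test asked for an equal rise, which the offset, by shrinking changes of dim transcripts, need not leave. It cannot decide, so a lower share of spermatids stays open. A wrong subspecies label is argued against by positions of 0.544 and 0.562 between musculus at 0 and castaneus at 1, and, since domesticus arrays also lay at 0.492 and 0.532, by a regression that gave castaneus coefficients of 0.497 and 0.527 against domesticus coefficients of 0.114 and 0.0885. Array brightness as the whole cause is argued against: after quantile normalization the round and elongating spermatid, Sertoli and Leydig lists stayed called between the reciprocal F1 at the preset correlation (medians -0.85, -0.50, 0.70 and 0.96), and 65% of reciprocal calls stayed called in 1 direction, against a bound of 50% set once that share was known. The other calls were lost or turned, the spermatogonial list was no longer called (adjusted p of 0.0694) and the split of directions moved from 4836 higher and 2851 lower to 2740 and 3379, so a part played by brightness stays open. An exchange of the labels of the 2 reciprocal F1 cannot be told apart from the labels as given (slope 0.121, interval -0.686 to 1.24, over 5 X-linked probe sets), so it stays open. Among single X-linked genes, Atp7a followed the labels, with 104.5 in musculus, 10.5 in castaneus, 315 with a musculus mother and 15.5 with a castaneus mother. Mid1, at the pseudoautosomal boundary, was higher with a musculus mother in testis (611.5 against 93) and in brain (1122 against 196), although castaneus exceeded musculus. In liver it was at 383 ± 103 with a musculus mother and 488.5 ± 74 with a castaneus mother (SD, n = 2). Atp7a and Mid1 were both named for large differences and decide nothing alone. Age acting alike on all genotypes is argued against: in the round and elongating spermatid, spermatogonial, Sertoli and Leydig lists, both arrays of this F1 lay outside the 8 arrays of its parents at 47 days, the castaneus x musculus F1 at 54 and the musculus x domesticus F1, also at 53, by at least 2.38 replicate SDs. The values of these lists had been seen before this test was chosen, and the pachytene and peritubular or macrophage lists were left out of it. From the F1 of the same age alone the gap was at least 2.93 replicate SDs. An effect of the direction of the cross, a change of expression within cells and an effect of age particular to this F1 stay open as untested.

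Nonadditive calls lay mostly above the midparent. A midparent taken on the log2 scale lies below the mean of the parental signals, and against a linear midparent 0%, 4.92% and 3.62% of the calls above it remained in brain, liver and testis of the domesticus cross. In brain and liver of the castaneus cross 0.741% and 8.7% remained, so the scale is a candidate explanation for the excess in these 5 comparisons. In testis of the castaneus cross 60.2% of the calls above it remained, so the scale alone does not account for most of those calls. The excess itself did not remain there: 829 above and 436 below the log2 midparent became 499 above and 627 below the linear one (44.3% above), so the scale is a candidate explanation for the excess in this tissue too. On the log2 scale the musculus x castaneus F1 alone gave 1911 nonadditive calls in this tissue and the castaneus x musculus F1 alone 159, whereas dominance acting alike in both F1 would give similar counts, so the calls there rest largely on the musculus x castaneus F1.

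Several of the largest parental differences rested on 1 probe set while other probe sets of the gene lay near 0. If probes designed on a mostly domesticus reference dimmed musculus and castaneus alike, the share of calls higher in domesticus would exceed the matching castaneus share. The bound chosen beforehand was over 10 points in each tissue, and the excess was 5.5 points in brain, 3.3 in liver and -1.3 in testis. These values argue against a shift of direction from such a shared dimming beyond that bound. A smaller shift, from mismatches in fewer probe sets, stays open, as do mismatches in domesticus and musculus alike. Mismatches in musculus alone would raise both shares and cancel in the excess, so this test cannot decide on them. Among calls of at least 2-fold, the other probe set moved alike in 17.1%, 35.8% and 34.6% of domesticus calls and 15.3%, 34.2% and 35.1% of castaneus calls in brain, liver and testis, against 52.7% for reciprocal calls in testis of the castaneus cross. The smallest shortfall was 16.9 points and the largest 37.4, on both sides of the bound of 20, so probe mismatch and differences in transcript level or isoform cannot be told apart here.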

How the results depend on the processing

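Chosen after the data were seen were the linear midparent, the lists for each F1 alone and the tissue dependence of reciprocal differences. Of 361 alternative values of 29 summary results, 241 stayed within 1.5 times the value reported and 120 did not; of 2170 for named genes and list calls, 1791 kept direction and side of the threshold. For values that moved the cause was not tested, except that fewer arrays or a wider adjustment leave less power by construction. Less power does not account for counts that rose with fewer arrays. For example, nonadditive calls in brain of the castaneus cross went from 146 to 230 with only the 8 arrays of the cross. Dim signals near the offset limit what could be called, and the alternative that leaves out sex-linked and mitochondrial probe sets was not run, for want of positions.

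With only the 8 arrays of the cross, reciprocal calls of the domesticus cross were 3, 9 and 33 in brain, liver and testis, and the castaneus cross had 230 nonadditive calls in brain, 0 and 1 reciprocal calls in brain and liver (limma), and 0 and 1 transgressive calls in liver and testis. With the musculus-mother F1 alone, brain of the domesticus cross had 71 nonadditive calls, and the castaneus cross had 0 transgressive calls in liver and 1911 nonadditive and 3833 transgressive in testis. With the musculus-father F1 alone, nonadditive calls were 89 in brain of the domesticus cross and 64, 135 and 159 in brain, liver and testis of the castaneus cross, with 1 transgressive call in testis. Adjusted over all tested probe sets, nonadditive calls were 35, 47 and 110 in the domesticus cross and 35 and 54 in brain and liver of the castaneus cross. Against the linear midparent they were 2, 28 and 14, and 10 and 61, and Lpcat2b in testis turned to -0.142 (domesticus cross) and -0.197 (castaneus cross).

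With no filter, reciprocal calls were 5 and 0 in brain and liver of the castaneus cross and 11 in liver of the domesticus cross, transgressive calls in testis 60 and tissue-dependent domesticus differences 3874. With an offset of 1 the liver of the castaneus cross had 1 reciprocal call. Quantile normalization gave 776 transgressive calls in testis and 2314 tissue-dependent reciprocal differences in the castaneus cross. Without an intensity trend, reciprocal calls were 3 and 26 in liver and testis of the domesticus cross and 1 in liver of the castaneus cross, with 1 transgressive call in testis. Without the animal block the tissue tests gave 1304 and 1356 parental and 95 and 1541 reciprocal calls. With the replicate number as a block, reciprocal calls in liver of the domesticus cross were 13. Of 141 named calls 4 were lost, and of 76 list calls 0. Replicate numbers paired the males of different genotypes in no uniform way, with correlations from -0.466 to 0.561. Their medians were 0.132, 0.0979 and 0.0953 in brain, liver and testis. With this block, brain parental calls went from 1553 to 1746 (domesticus) and from 1640 to 1854 (castaneus). An effect shared by replicate number therefore stays open. Of the 76 list calls, 3 held with an estimated correlation and 25 with fry, which called 35 lists in all. With the musculus-father F1 alone, pancreas genes in liver of the domesticus cross were at -0.441, and in testis of the castaneus cross Sertoli genes were at 0.0147 and Leydig genes at -0.000956.

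Leaving out each array in turn, with the lone replicate assumed to vary like the other groups, gave these ranges. Parental calls were 700 to 853, 769 to 1135 and 2039 to 2265 in brain, liver and testis (domesticus) and 724 to 1084, 745 to 1186 and 2130 to 2356 (castaneus). Nonadditive calls were 86 to 142, 92 to 264 and 160 to 259, and 116 to 195, 155 to 261 and 621 to 1150. Transgressive calls were 0 in each tissue of the domesticus cross, and 0 to 9, 0 to 2 and 1 to 449 in the castaneus cross. Reciprocal calls were 2 to 4, 0 to 5 and 6 to 38, and 0 to 52, 0 to 28 and 3447 to 7625. Tissue dependence gave 1389 to 1656 and 1416 to 1774 parental and 84 to 321 and 830 to 2602 reciprocal calls. Of 141 named calls, 29 were lost in at least 1 of these fits and 0 reversed.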

Other observations

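The observations on single arrays and the slopes without Mid1 were chosen after the results were seen; the bounds for the maternal X chromosome were written before any slope was computed, and the demand that the whole interval clear a bound was added afterwards.

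In liver of the domesticus cross, circadian clock genes differed between reciprocal F1. Dbp, a clock output transcription factor, had a signal of 11170 ± 1975 with a musculus mother and 160 ± 1.41 with a musculus father (SD, n = 2), a log2 difference of 5.86 ± 1.08 that missed the threshold over all genes (limma adjusted p = 0.0623). Per3 was at 2.27, Per2 at 1.52 and Nr1d1 at 2.20, and Npas2 at -3.16. Of 16 clock genes, limma called 0 over all genes tested, and 8 higher and 4 lower adjusted over the list alone (list adjusted p of 0.00293, adjusted p = 0.131 with an estimated correlation). The 20 cholesterol synthesis and uptake genes were lower in the same contrast, with a median of -0.67, 0 called by limma over all genes and 10 lower adjusted over the list alone (adjusted p of 1.13e-08, adjusted p = 0.437 with an estimated correlation), among them Mvd (-2.54), Mvk (-1.59) and Fdft1 (-1.18). Relative to the mean of the liver arrays, the cholesterol list lay at -0.781 and -0.233 on musculus x domesticus F1 replicates 1 and 2 and at 0.00511 and 0.0769 on those of the domesticus x musculus F1. In the same contrast 12 exocrine pancreas genes had a median of 2.32 (adjusted p of 2.72e-06, 0 called by limma over all genes or the list alone, adjusted p = 0.724 with an estimated correlation), with that list at 0.969 and 1.5 in the musculus x domesticus F1 and at -1.38 and -1.16 in the domesticus x musculus F1. The labels give no hour of collection. The 34 interferon response genes of liver in the castaneus cross had a median of -0.35 from the midparent, with 0 called over all genes by limma and 1 higher and 11 lower adjusted over the list alone (adjusted p of 3.17e-08, adjusted p = 0.37 with an estimated correlation).

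In testis of the castaneus cross, 13 of 30 imprinted genes were higher and 1 lower with a musculus mother (14 and 1 adjusted over the list alone, adjusted p of 0.0189, adjusted p = 0.306 with an estimated correlation). Plagl1 was higher by 1.52, Peg3 by 1.12, Ndn by 1.12 and Igf2 by 1.03, and Cdkn1c was lower (-0.78). After quantile normalization the list had a median of 0.28. Of 20 glutathione S-transferase genes, 9 were higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p of 0.02, adjusted p = 0.332 with an estimated correlation), with Gstm6, also on the Sertoli list, at 1.33 and Gsta4, also on the Leydig list, at 0.99. Of 8 antigen presentation genes 4 were higher, including B2m at 0.96 (6 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). Round spermatid transcripts were lower and Sertoli and Leydig transcripts higher in the same contrast.

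Single arrays stood apart for some genes. In liver, pancreas transcripts were high on the array of musculus x castaneus F1 replicate 2, with Zg16 at 14760, Ctrb1 at 14030, Cela1 at 17223 and Prss2 at 7508, where replicate 1 had 213, 398, 2150 and 487. The pancreas list lay at a median of 1.99 above the midparent in that cross (8 of 12 higher adjusted over the list alone, adjusted p = 0.37 with an estimated correlation). In brain, domesticus replicate 1 had Fos at 447, Arc at 207 and Nr4a1 at 640, and replicate 2 had 3761, 2042 and 3349. Immediate early genes lay at a median of 0.40 above the midparent in that cross (0 of 20 called by limma over all genes or the list alone, adjusted p of 2.64e-06, adjusted p = 0.762 with an estimated correlation).

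F1 males carry only their mother's X chromosome, so a hypothesis was that parental differences of X-linked genes recur between reciprocal F1. In the domesticus cross the slope of the reciprocal on the parental difference was 0.832 (interval 0.648 to 0.941) over 50 X-linked entries from 38 genes. An entry is 1 probe set in 1 tissue. Over the others it was -0.00853. Such slopes would arise from expression that follows the maternal X, as for Trappc2. Large differences weigh most in the slope, and it was not computed without Trappc2. In the castaneus cross the slope was 0.142, under the bound of 0.25 that was to count against the hypothesis. Its interval of -0.116 to 0.516 over 76 such entries from 57 genes reached past both bounds, so the test decided nothing there. Mid1, higher in castaneus than in musculus yet higher in brain of F1 with a musculus mother, weighed heavily. It lies at the pseudoautosomal boundary, so it may not be carried on the maternal X alone. Without Mid1 the slope was 0.404 in all tissues, 0.551 in brain and liver and 0.0601 in testis. X linkage was assigned by hand from gene symbols, since no chromosome table was used.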
